A study of Mus musculus with 16 samples.

How the data were processed

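CJ9 mouse embryonic stem cells, WT or arid4b-delta, were directed to endoderm or mesoderm for 5 days, fixed for 8 min with formaldehyde and profiled by ChIP-seq for H3K4me3, H3K27me3 and H3K27ac, per the labels. Libraries were made with a NEBNext kit and sequenced on a HiSeq2000. Of the 16 samples, 12 are ChIP libraries with a peak list each, 1 per mark, lineage and genotype. The 4 input DNA samples have no file here and were not used. Per the submitters' processing notes, the authors used Bowtie2, Picard and MACS2 on build mm10, with no versions or settings stated.

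H3K4me3 and H3K27ac came as narrow peaks and H3K27me3 as broad peaks, called in each library separately. Column 5 of each deposited list is the score that the authors' peak caller gives a peak. Column 7 is the authors' fold enrichment of the peak, a ratio over control or local background. Columns 8 and 9 are the authors' -log10 p and -log10 q values per peak, and in the narrow peak lists column 10 is the summit position in bp from the peak start, another unit set by the authors. The lowest -log10 q was 2.00 in the narrow lists and 0.307 in the broad lists. Scores and -log10 p values were not used further, and -log10 q values only to rank peaks of equal fold and to describe a few weak peaks. Folds depend on each library's background and were never compared between lists beyond printing them. Depth is not given by a peak list, so no value here is scaled to it.

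Peaks were joined to 21887 protein-coding genes on chromosomes 1 to 19, X and Y of a RefSeq table of build GRCm38.p6, which is mm10. The table gives gene starts and ends without strand or transcripts, so the plan to use every transcript's TSS could not be followed. The promoter end of a gene was taken as the end with more H3K4me3 coverage within 1000 bp, summed over the 4 H3K4me3 libraries. This assigned 13145 genes, 11876 genes having H3K4me3 at one end only and 1284 at both, and the 8742 genes with no coverage or a tie kept both ends. H3K27ac, which took no part in the choice, lay at the assigned end of 53.3% of these genes in WT and 53.8% in arid4b-delta, and at the other end of 4.15% and 4.55%. Gene ends include predicted models, so the annotated end of some genes, such as Actb, lies away from the promoter in use, and whether a peak lies in an exon or an intron is not known.

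A promoter was marked when a peak overlapped the 1000 bp either side of its end by at least 1 bp. Marked promoters were compared between genotypes within each lineage and mark, and between lineages within a genotype. Peaks were shared when they overlapped by at least 1 bp. Each promoter was also classed by H3K4me3 and H3K27me3, and H3K27ac peaks over 2500 bp from any gene end were called distal, with those within 20000 bp of a promoter counted per listed gene. With 1 library per group there was no test between groups. Shares carry exact Clopper-Pearson 95% intervals.

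The lists, the rule for named genes, the comparisons and most alternatives were set before the data were examined. There were 16 gene lists: naive pluripotency, general pluripotency, primed epiblast, primitive streak and mesendoderm, endoderm, mesoderm, neuroectoderm, extraembryonic endoderm, trophoblast, germline, fibroblast (feeder cells), housekeeping, Hox clusters, Polycomb components, Sin3-HDAC complex, and Nodal, Wnt, BMP and FGF signalling. All 339 entries matched the gene table, giving 327 distinct genes. For each of the 96 combinations of list, mark and lineage, the count of promoters in one genotype only was set beside 10000 random lists of the same size, matched on the WT state of the 3 marks (seed 1). The share of random lists at least as high describes these libraries and is no p-value, and none was adjusted for the number of combinations.

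Named genes were taken by rule, per mark and lineage. The first part takes up to 20 listed genes, in list order and then by fold enrichment, whose promoter is absent from the other genotype's full list and present among the N highest peaks of its own, N being the length of the shorter list. The second part takes the 5 genes per direction with the highest fold enrichment and no peak of the other genotype within 5000 bp. Arid4b, Pou5f1, Nanog, Sox2, T, Mesp1, Kdr, Sox17, Foxa2, Gata4 and Gata6 were given whatever their values, and genes with predicted or unnamed symbols were counted but not named. A few other genes that meet the rule stay in the counts and are not reported here. Genes named outside this rule were chosen after their values were seen. Peak positions are given as first and last base.

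The alternatives set beforehand were lists matched in length, the upper 50% of each list by fold enrichment, windows of 500 and 2500 bp, at least 500 bp of the window covered, peaks of at least 500 bp, chromosomes 1 to 19 only, 50% of a peak covered, peaks within 1000 bp, and distal beyond 5000 bp. Those added after the data were seen were either gene end, ends assigned from WT only, a peak anywhere in the gene or within 1000 bp of it, and absence from both lists of the other genotype. For gene lists, the 2500 bp window was also added then. The code was tested on simulated peak lists over 5485 genes. It recovered 100% of 200 simulated arid4b-delta-only promoters and 100% of 200 WT-only promoters with 0 calls elsewhere, and it assigned 100% of promoter ends correctly. These genes were chosen with ends far from every other gene end and given H3K4me3 only at the simulated promoter end. The simulation therefore checks the code and does not cover crowded genes, genes marked at both ends or promoters away from the annotated end. Of 500 random lists 3% fell in the highest 5%, and a planted list was reached by 0.02% of random lists. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.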

Results

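Chromatin was profiled by ChIP-seq in CJ9 cells, a mouse embryonic stem cell line, after 5 days of directed differentiation to endoderm or to mesoderm. Wild-type cells (WT) were set beside cells that carry a deletion in Arid4b, labelled arid4b∆ and written arid4b-delta here. Arid4b encodes a subunit of the Sin3-HDAC corepressor complex, which removes acetyl groups from histones. The marks were H3K4me3, found at active and poised promoters, H3K27ac, found at active promoters and enhancers, and H3K27me3, the mark of Polycomb repression. Each of the 3 marks was measured in both genotypes and both lineages with 1 library per group, which gives 12 peak lists. With 1 library per group there are no replicates, so no difference between genotypes was tested and no p-values are given. Sequencing depth is unknown, because a peak list holds no read totals. The lists held 6150 to 35884 peaks, and exact Clopper-Pearson 95% intervals on shares cover counting error only. The fold enrichment of a peak is the authors' own value and was used only to describe and rank peaks within a list.

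Arid4b itself (gene 94246, chromosome 13, 14063609 to 14199603, mm10) had promoter peaks in every H3K4me3 and H3K27ac library and in none of the H3K27me3 libraries. Its H3K4me3 fold enrichment was 11.4 in WT and 26.9 in arid4b-delta endoderm, and 16.0 and 27.1 in mesoderm. Its H3K27ac fold enrichment was 16.4 and 20.2 in endoderm, and 22.8 and 29.3 in mesoderm. The labels do not say which part of the gene was deleted, so these peaks do not check the genotype.

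The series title places Arid4b in lineage commitment, and the comparison of genotypes within each lineage asks which promoters carry a mark in one genotype and not in the other. H3K4me3 and H3K27me3 marked more promoters in arid4b-delta in both lineages, over 21887 protein-coding genes. H3K4me3 was in arid4b-delta only at 1178 endoderm promoters against 22 in WT only, and at 864 mesoderm promoters against 26. H3K27me3 was in arid4b-delta only at 1024 endoderm promoters against 418, and at 1640 mesoderm promoters against 149. H3K27ac differed in both directions, with 970 promoters in arid4b-delta only and 1018 in WT only in endoderm, and 1210 and 800 in mesoderm.

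The share of differing promoters that were marked in arid4b-delta only was 98.2% (95% interval 97.2 to 98.8) for endoderm H3K4me3, 97.1% (95.7 to 98.1) for mesoderm H3K4me3, 71.0% (68.6 to 73.3) for endoderm H3K27me3 and 91.7% (90.3 to 92.9) for mesoderm H3K27me3. For H3K27ac it was 48.8% (46.6 to 51.0) in endoderm and 60.2% (58.0 to 62.3) in mesoderm. Most WT H3K4me3 peaks overlapped an arid4b-delta peak (98.1% in endoderm and 97.6% in mesoderm), while 65.4% and 65.9% of the arid4b-delta peaks overlapped a WT peak. For H3K27me3 these overlaps were 53.9% and 68.6% of WT peaks and 30.1% and 30.8% of arid4b-delta peaks, and for H3K27ac 70.8% and 73.2% against 27.02% and 40.6%. The arid4b-delta list was the longer of each pair, and matching the 2 lists in length turned the endoderm H3K27me3 share to 36.2% and the mesoderm H3K27ac share to 26.2%, while both H3K4me3 shares and the mesoderm H3K27me3 share (61.1%) stayed above 50%. The direction of the endoderm H3K27me3 and the mesoderm H3K27ac totals therefore depended on which peaks of the longer list were kept. The near-even endoderm H3K27ac share depended on the lists as well, at 19.7% in matched lists and 68.4% in the upper 50% of each list by fold enrichment.

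**Figure D1:**
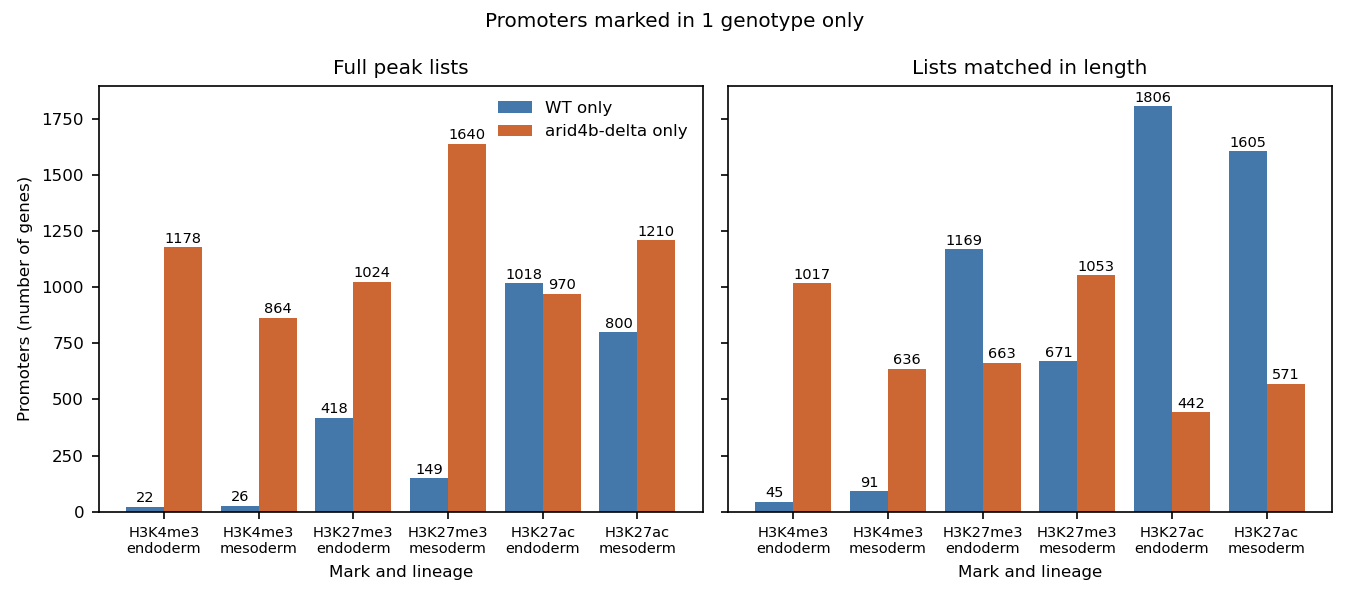
Number of promoters (vertical axis, genes) marked in WT only (blue) or in arid4b-delta only (orange) for each mark and lineage (horizontal axis), with the full peak lists on the left and lists matched in length on the right. H3K4me3 was mostly in arid4b-delta only in both panels (1178 and 1017 endoderm promoters), while endoderm H3K27me3 and mesoderm H3K27ac changed direction in matched lists.

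In mesoderm, promoters of some pluripotency genes carried H3K27ac in arid4b-delta and not in WT. The general pluripotency list of 16 genes had H3K27ac at 7 promoters in WT and 13 in arid4b-delta. The 6 that differed included Utf1, a chromatin factor of undifferentiated stem cells (gene 22286, peak at chromosome 7, 139945157 to 139946221, fold enrichment 11.8), L1td1, a pluripotency RNA-binding protein (gene 381591, chromosome 4, 98727580 to 98728093, 12.1), Tdgf1, a Nodal co-receptor (gene 21667, chromosome 9, 110946426 to 110947606, 10.7), and Myc (gene 17869, chromosome 15, 61984919 to 61985088, 7.30). Of the 11 primed epiblast genes, 5 were acetylated in arid4b-delta only: Fgf5 (gene 14176, chromosome 5, 98253747 to 98255202, 12.1), Pou3f1 (gene 18991, 11.2), Sall2 (gene 50524, 7.39), Otx2 (gene 18424, 7.10) and Sox3 (gene 20675, 6.93), all transcription factors apart from the growth factor Fgf5. Pou5f1, the pluripotency factor Oct4, had H3K27ac in both genotypes, with fold enrichment 10.5 in WT and 29.3 in arid4b-delta.

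Promoters of some primitive streak and mesoderm genes carried mesoderm H3K27ac in WT and not in arid4b-delta. In the primitive streak and mesendoderm list of 22 genes, T, which encodes Brachyury (gene 20997, chromosome 17, 8433798 to 8433954, fold enrichment 6.77), Tbx6 (gene 21389, chromosome 7, 126784820 to 126785131, 7.73), Cdx2 (gene 12591, chromosome 5, 147306537 to 147306796, 7.11) and the somite regulator Mesp2 (gene 17293, chromosome 7, 79810904 to 79811139, 5.57) were acetylated in WT only, against Nodal in arid4b-delta only. All 5 acetylated promoters of the 34 mesoderm genes were in WT only: Foxc1 (gene 17300, chromosome 13, 31806890 to 31807677, 9.76), Dll1 (gene 13388, 9.41), Twist1 (gene 22160, 7.76), Pdgfra (gene 18595, 6.40) and Dll3 (gene 13389, 6.18). In the signalling list of 32 genes (Nodal, Wnt, BMP and FGF pathways) WT alone had H3K27ac at Smad6, Fzd10, Bmp7, Wnt5a and Fgf10, and 2 genes were in arid4b-delta only. Lef1 and Cdh2, listed as primed epiblast genes, were likewise in WT only: Lef1, a Wnt-pathway transcription factor (gene 16842, chromosome 3, 131110224 to 131112337, 13.3), and Cdh2, or N-cadherin (gene 12558, 10.1). Dll1, Twist1, Pdgfra, Dll3, Nodal and the 5 signalling genes fell outside the rule for named genes and were chosen after their values were seen.

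Each list was set beside 10000 random lists of the same size, matched on the WT state of the 3 marks. None of them reached the 6 arid4b-delta-only general pluripotency genes (random mean 0.632) or the 5 primed epiblast genes (0.584). In WT only, 0.14% of random lists reached the 4 streak genes (mean 0.934), 0.01% the 5 mesoderm genes (0.870) and 0.73% the 5 signalling genes (1.41). Sall2 had a WT peak 2412 bp away, and the other 19 genes named from the lists under the rule had none within 2500 bp. In lists matched in length these counts were 4, 5, 4, 5 and 5, and the shares in WT only became 1.44% for the streak, 0.29% for mesoderm and 14.2% for signalling. Utf1, L1td1, Tdgf1, Fgf5, Otx2 and Sall2 were also acetylated in WT endoderm, so against both WT lists 3 general pluripotency and 2 primed epiblast genes remained. Against both arid4b-delta lists 4 streak, 5 mesoderm and 3 signalling genes remained in WT only.

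In the full lists, random lists reached the mesoderm H3K27ac counts of the other lists more often than those above. In matched lists this did not hold for the Hox count in WT only, which 5.88% reached, against 14.2% for signalling. The naive pluripotency list had Nanog in arid4b-delta only (gene 71950, 8.65) and Tbx3 in WT only (gene 21386, 5.45). The endoderm list of 25 genes had Cldn6, a tight-junction claudin, and Krt18 in arid4b-delta only and Foxa3 in WT only. WT alone had 4 Polycomb components, among them Pcgf1, Epop and Cbx8, a count that 21.9% of random lists reached. In matched lists it was 5, which 50.3% reached. WT alone also had Hoxa4, Hoxb8 and Hoxb2, a Hox count that 1.85% reached (5.88% in matched lists) and that became 8 with a window of 2500 bp. Nes and Ogt were in arid4b-delta only, and Irx3, Vim and Brms1 in WT only. Housekeeping genes had 16 acetylated promoters of 20 in both genotypes, extraembryonic endoderm genes 1 of 13 in both, and germline genes 0 of 16. The strongest H3K27ac promoter peaks with none in the other genotype within 5000 bp were at Tmem154, Frmd5, Cldn6, Pyurf and Spint2 in arid4b-delta (fold enrichment 23.5 to 17.3) and at Dyrk1b, Fignl2, Lrr1, Sptssa and Prkd1 in WT (17.2 to 13.8).

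**Figure D2:**
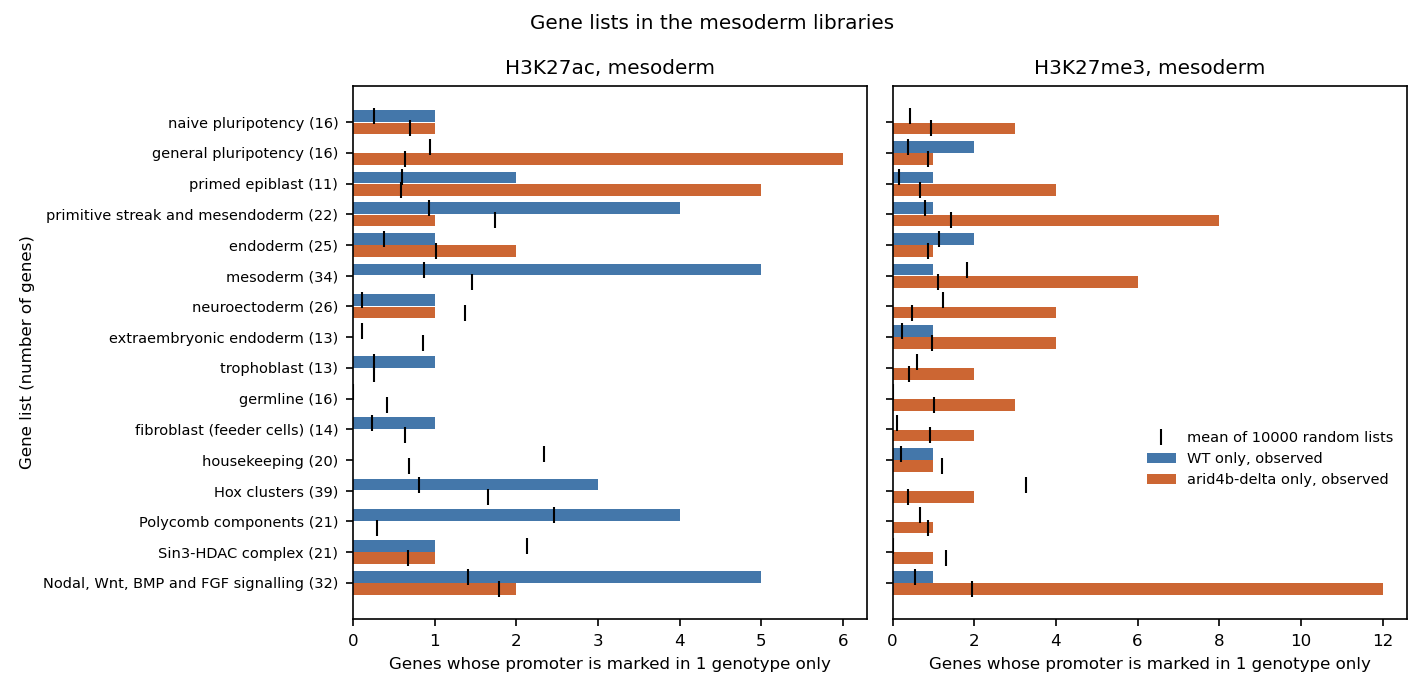
Number of genes per list whose promoter was marked in WT only (blue bars) or in arid4b-delta only (orange bars) in mesoderm (horizontal axis, genes) for each gene list (vertical axis, list size in brackets), with the mean of 10000 random lists as a black tick, for H3K27ac on the left and H3K27me3 on the right. General pluripotency H3K27ac (6 genes) and signalling H3K27me3 (12 genes) were in arid4b-delta only, against random means of 0.632 and 1.95.

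H3K27me3 in mesoderm lay in arid4b-delta, and not in WT, at some genes of the primitive streak, of mesoderm and of inductive signalling. The WT mesoderm list was the shortest H3K27me3 list, with 6150 peaks and 1952 marked promoters. WT endoderm had 3026 marked promoters, and arid4b-delta 3632 in endoderm and 3443 in mesoderm. Calls in arid4b-delta only may thus reflect the low WT list. Among the 22 streak genes, 10 were marked in WT and 17 in arid4b-delta. The 8 in arid4b-delta only included the Wnt-responsive factor Sp5 (gene 64406, chromosome 2, 70472124 to 70479665, fold enrichment 4.11), Evx1 (gene 14028, chromosome 6, 52306394 to 52324361, 2.48), Mixl1 (gene 27217, chromosome 1, 180695792 to 180698471, 2.34), Mesp2 (2.19) and Wnt3 (gene 22415, 2.12), with Mesp1 (1.89) and T (1.64) among the weaker peaks. Of the 34 mesoderm genes, 21 were marked in WT and 26 in arid4b-delta, with the EMT regulator Snai1 (gene 20613, 3.66) and the Notch ligand Dll1 (3.28) among the 6 in arid4b-delta only. The signalling list had 9 marked promoters in WT and 20 in arid4b-delta, with 12 in arid4b-delta only, among them the Wnt inhibitor Dkk1 (gene 13380, chromosome 19, 30550463 to 30550672, 7.56). Sp5 and Wnt3 are in both the streak and the signalling lists, and Bmp4 in both the mesoderm and the signalling lists.

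Some genes carried mesoderm H3K27me3 in WT only. They included Utf1 (chromosome 7, 139943737 to 139946269, fold enrichment 2.29), Sox2 (gene 20674, 2.19), Fgf5 (3.29), Nodal (gene 18119, 4.38) and, from the endoderm list, Epcam (gene 17075, 1.94) and Cldn6 (1.34). The peaks were 194 bp long at Sox2, 228 bp at Fgf5, 245 bp at Nodal and 146 bp at Epcam, against a list median of 582.5 bp. The -log10 q was 0.773 at Epcam and 0.834 at Cldn6. Short peaks in arid4b-delta only included those at Dkk1 (210 bp) and Lin28a (222 bp). In arid4b-delta only were the primed epiblast genes Cdh2 (4.75), Zic2 (3.44) and Lef1 (3.17), the naive pluripotency genes Tfcp2l1 (2.42), Nr0b1 (2.18) and Klf5 (2.12), and Lin28a (2.14).

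No random list reached 8 streak genes (random mean 1.44) or 12 signalling genes (1.95), and 0.05% reached 6 mesoderm genes (1.10). The shares were 0.02% for the 4 neuroectoderm genes Neurod1, Irx3, Zic1 and Nes, 0.16% for the 4 primed epiblast genes and 0.72% for the 4 extraembryonic endoderm genes. WT peaks lay 1879 bp from Cdh2, 2187 bp from Sp5 and 2382 bp from Evx1. In lists matched in length the streak, mesoderm and signalling counts were 5, 5 and 9, against 2, 3 and 3 in WT only. Most of these promoters carried H3K27me3 in WT endoderm, so against both WT lists the 3 counts were 2, 1 and 2. The neuroectoderm, primed epiblast and extraembryonic endoderm counts were 3, 3 and 1 in matched lists, where 47.5% of random lists reached the last, and 0, 2 and 1 against both WT lists. In WT only the matched counts were 4, 2 and 1, which turned the neuroectoderm direction. Fewer differences fell in the naive pluripotency (4 marked in WT, 7 in arid4b-delta), general pluripotency (4 and 3), endoderm (14 and 13), Hox (37 and 39), trophoblast (6 and 8), germline (0 and 3), fibroblast (2 and 4), housekeeping (1 and 1), Polycomb (4 and 5) and Sin3-HDAC (0 and 1) lists. The strongest H3K27me3 promoter peaks in arid4b-delta only were at Nsun7, Trp53i11, Glt28d2, Dkk1 and Dpf1 (fold enrichment 9.38 to 7.56), and those in WT only at Cxcl5, Car4, Nodal, Adgrf2 and Tubb4a (4.86 to 3.58).

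**Figure D3:**
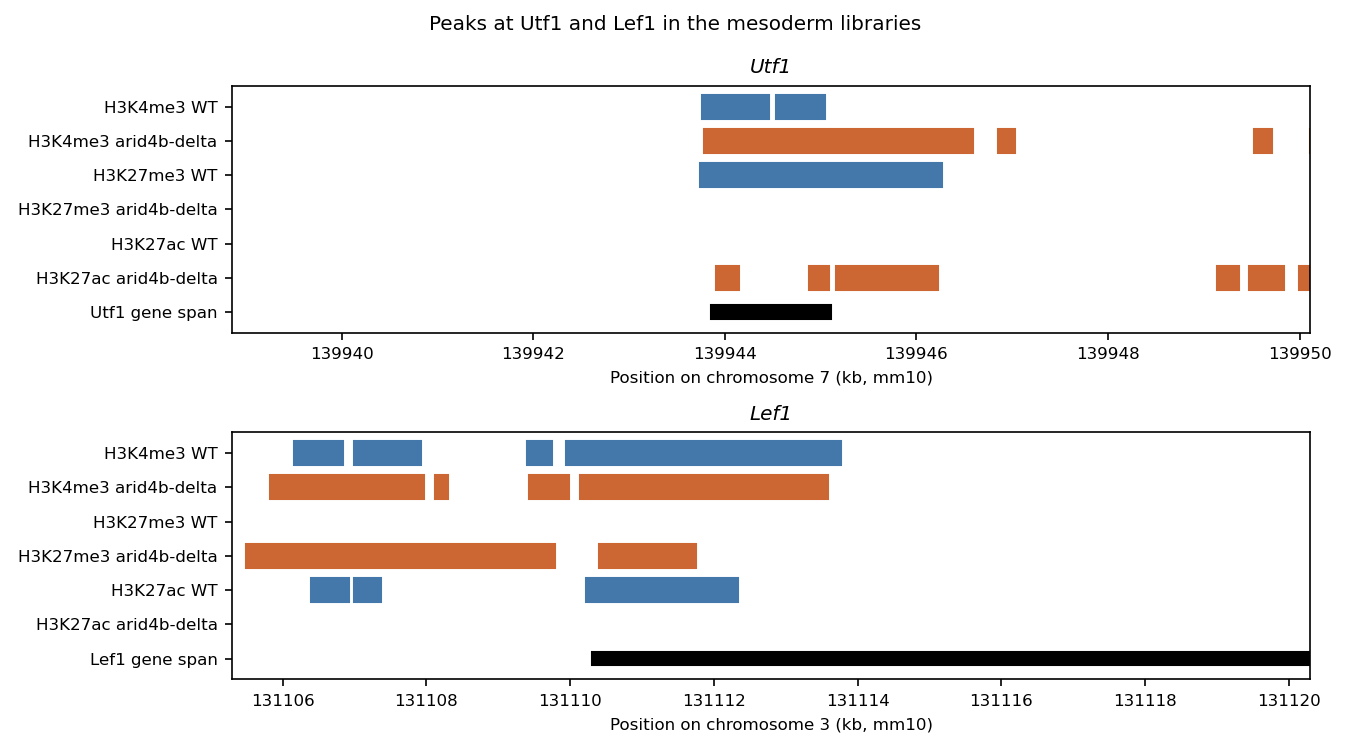
Mesoderm peaks of the 3 marks in WT (blue) and arid4b-delta (orange) at Utf1 on chromosome 7 and Lef1 on chromosome 3 (horizontal axes, position in kb, mm10), with the annotated gene span in black. At the Utf1 promoter WT had H3K27me3 and arid4b-delta had H3K27ac, while at the Lef1 promoter WT had H3K27ac and arid4b-delta had H3K27me3.

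Mesoderm H3K4me3 was at most listed promoters in both genotypes. Nanog (gene 71950, chromosome 6, 122707600 to 122709345, fold enrichment 6.50), Zfp42, or Rex1 (gene 22702, 7.34), and Tdgf1 (6.89) had it in arid4b-delta only, while Wnt8a (gene 20890, chromosome 18, 34542305 to 34542954, 7.65) and Mesp2 (3.89) had it in WT only. The endoderm genes Sox17 (gene 20671, 6.44) and Krt19 (gene 16669, 8.43), the mesoderm genes Gata2 (gene 14461, 8.35) and Pax2 (gene 18504, 7.27), the collagen gene Col1a1 (gene 12842, 13.7) and the germline genes Ddx4 (gene 13206, 6.69) and Dnd1 (gene 213236, 5.53) were in arid4b-delta only. Sox17, the housekeeping gene Actb (gene 11461, 33.9) and Col1a1 had a WT peak within 2500 bp of the promoter end, at 1025, 1220 and 1266 bp. Hox promoters with H3K4me3 numbered 26 of 39 in WT and 30 in arid4b-delta, with 7 in arid4b-delta only (68.1% of random lists reached this) and Hoxa3, Hoxb5 and Hoxb3 in WT only (0.01%). In matched lists these Hox counts were 4 and 5, which turned their direction.

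In WT mesoderm and arid4b-delta mesoderm the H3K4me3 counts were 5 and 7 for naive pluripotency, 12 and 14 for general pluripotency, 10 and 10 for primed epiblast, 16 and 16 for the streak, 13 and 17 for endoderm, 21 and 24 for mesoderm, 24 and 26 for neuroectoderm, 6 and 8 for extraembryonic endoderm, 4 and 4 for trophoblast, 1 and 3 for germline, 6 and 7 for fibroblast, 18 and 19 for housekeeping, 19 and 21 for Polycomb, 21 and 21 for Sin3-HDAC and 26 and 28 for signalling genes. The 2 Polycomb genes were Aebp2 and Cbx7, a count that 0.36% of random lists reached. Among the strongest peaks in arid4b-delta only were those at Sntg2, Pacsin1, Fhad1 and Elapor1 (17.5 to 14.3), and those in WT only at Eif2s3y, Ifitm1, Ddx3y, Wnt8a and Uty (11.0 to 7.63), of which Eif2s3y, Ddx3y and Uty are on chromosome Y.

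In endoderm, H3K27ac at the listed genes differed little between genotypes. Nanog had a promoter peak in WT only (chromosome 6, 122707618 to 122707820, fold enrichment 5.95), and Foxd3 (gene 15221, 6.25), the organizer gene Gsc (gene 14836, 4.56), the keratin genes Krt8 (gene 16691, 5.25) and Krt18 (gene 16668, 4.16) and the BMP pseudoreceptor Bambi (gene 68010, 12.05) were also in WT only. Myc (7.89), the matrix gene Fn1 (gene 14268, 8.87) and the Polycomb gene Aebp2 (gene 11569, 6.57) were in arid4b-delta only. None of the 34 mesoderm, 26 neuroectoderm, 39 Hox or 13 trophoblast genes had promoter H3K27ac in either genotype. Sox17, Foxa2, Gata4 and Gata6, factors that specify endoderm, and Kdr and Mesp1, expressed in early mesoderm, had no promoter H3K27ac in any of the 4 libraries.

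The endoderm H3K27ac counts in WT and arid4b-delta were 1 and 0 for naive pluripotency, 11 and 10 for general pluripotency, 5 and 7 for primed epiblast, 3 and 2 for the streak, 4 and 2 for endoderm, 1 and 1 for extraembryonic endoderm, 0 and 1 for germline, 0 and 1 for fibroblast, 16 and 14 for housekeeping, 13 and 13 for Polycomb, 17 and 16 for Sin3-HDAC and 11 and 10 for signalling genes. The highest count against random lists was that of the 2 primed epiblast genes in arid4b-delta only, Dnmt3b and Pou3f1, which 3.39% reached and which was 0 in matched lists. Sdha, Actb, Cbx2 and Tet1 were in WT only. Within 2500 bp of the promoter end, Bambi, Tet1 and Actb had a peak in arid4b-delta, at 1030, 1129 and 1251 bp, and Aebp2 had a WT peak at 1302 bp. The strongest promoter peaks were at Aven, Zxdb, Adrm1, Rapgef1 and Lrp6 in arid4b-delta only (20.9 to 15.3) and at Mospd3, Magi3, Pdha1, Hdhd2 and Map2k4 in WT only (18.7 to 12.1).

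Most listed promoters with endoderm H3K27me3 had it in both genotypes. All 39 Hox and all 26 neuroectoderm promoters were marked in both. Wnt3, an inducer of the primitive streak, carried it in arid4b-delta only (chromosome 11, 103774450 to 103775500, fold enrichment 11.5), under a peak that also covers the gene end of Wnt9b. Snai1 (3.80), Tbx5 (gene 21388, 2.67) and Etv2 (gene 14008, 2.39) were in arid4b-delta only in the mesoderm list, and Thbd, Pth1r and Lamb1 (3.59, 2.99 and 1.88) in the extraembryonic endoderm list. Utf1 (1.97), Sox3 (1.94), Tbx6 (1.495) and Krt19 (4.01) were in WT only. The share of random lists that reached the arid4b-delta-only count was 0.28% for the 4 mesoderm genes, 0.32% for the 3 extraembryonic endoderm genes and 0.52% for the 3 streak genes. In matched lists these counts were 3, 3 and 1, against 3, 5 and 5 in WT only, so the extraembryonic endoderm and streak directions turned. Tbx5 and Pth1r had WT peaks 1144 and 1015 bp from the promoter end. The peaks in arid4b-delta only were 146 bp long at Thbd and 176 bp at Etv2, against a list median of 523 bp. The WT-only peak at Tbx6 was 187 bp, against a median of 542 bp. The -log10 q was 1.18 at Lamb1 in arid4b-delta only, and 1.13 at Utf1, 1.01 at Sox3 and 1.15 at Tbx6 in WT only.

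Promoters with endoderm H3K27me3 in WT and in arid4b-delta numbered 7 and 7 for naive pluripotency, 4 and 3 for general pluripotency, 4 and 4 for primed epiblast, 15 and 17 for the streak, 13 and 14 for endoderm, 24 and 28 for mesoderm, 6 and 9 for extraembryonic endoderm, 7 and 8 for trophoblast, 0 and 3 for germline, 3 and 5 for fibroblast, 0 and 2 for housekeeping, 5 and 5 for Polycomb, 3 and 2 for Sin3-HDAC and 17 and 20 for signalling genes. The strongest in arid4b-delta only were at Wnt3, Wnt9b, Gstm5, Mga and Mansc1 (11.5 to 9.97), and in WT only at Aifm2, Ugt2b1, Kmt5c, Tarbp1 and Ambra1 (6.30 to 5.04). The shortest of these peaks were at Tarbp1 (148 bp) and Kmt5c (157 bp).

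Endoderm H3K4me3 was at more Hox, neuroectoderm and mesoderm promoters in arid4b-delta than in WT. Hox promoters with the mark numbered 8 of 39 in WT and 25 in arid4b-delta. Neuroectoderm promoters numbered 18 of 26 and 25, with Nkx2-2 (gene 18088, chromosome 2, 147193863 to 147195596, fold enrichment 12.5), En1 (gene 13798, 11.7), Dlx5 (gene 13395, 8.07) and Pax6 (gene 18508, 7.31) among the 7 that differed. Mesoderm promoters numbered 17 of 34 and 22, with Osr1 (gene 23967, 7.17), Gata2 (7.16), Pax2 (6.22) and the cardiac factor Nkx2-5 (gene 18091, 4.71) in arid4b-delta only. Wnt3a (gene 22416, 12.9), Mesp1 (5.53), Sox17 (6.10), Krt19 (9.92) and Zfp42 (5.73) were also in arid4b-delta only, and Wnt8a (4.17) was in WT only.

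The Hox and mesoderm H3K4me3 counts were not high for promoters of the same WT state. For the 17 Hox genes 72.7% of random lists reached the count (mean 18.1), for the 7 neuroectoderm genes 8.57% did and for the 5 mesoderm genes 85.2%. In matched lists the 3 counts were 16, 7 and 4, and 4.74% of random lists reached the neuroectoderm count. Aebp2 and Cbx7, in arid4b-delta only as in mesoderm, were again reached by 0.36%. Nkx2-2 and Amn had WT peaks 1133 and 1251 bp away. Against both WT lists the Hox count was 4, the neuroectoderm count 1 and the mesoderm count 2. The remaining counts in WT and arid4b-delta were 6 and 7 for naive pluripotency, 13 and 13 for general pluripotency, 10 and 10 for primed epiblast, 14 and 15 for the streak, 14 and 15 for endoderm, 5 and 7 for extraembryonic endoderm, 3 and 4 for trophoblast, 0 and 1 for germline, 4 and 7 for fibroblast, 18 and 18 for housekeeping, 19 and 21 for Polycomb, 21 and 21 for Sin3-HDAC and 24 and 27 for signalling genes. Among the strongest peaks in arid4b-delta only were those at Fam124a, Ndnf, Mafa and Dio3 (20.9 to 15.3), and those in WT only at Uty, Eif2s3y, Rtl8a, Camk1g and Ddx3y (7.99 to 5.91).

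**Figure D4:**
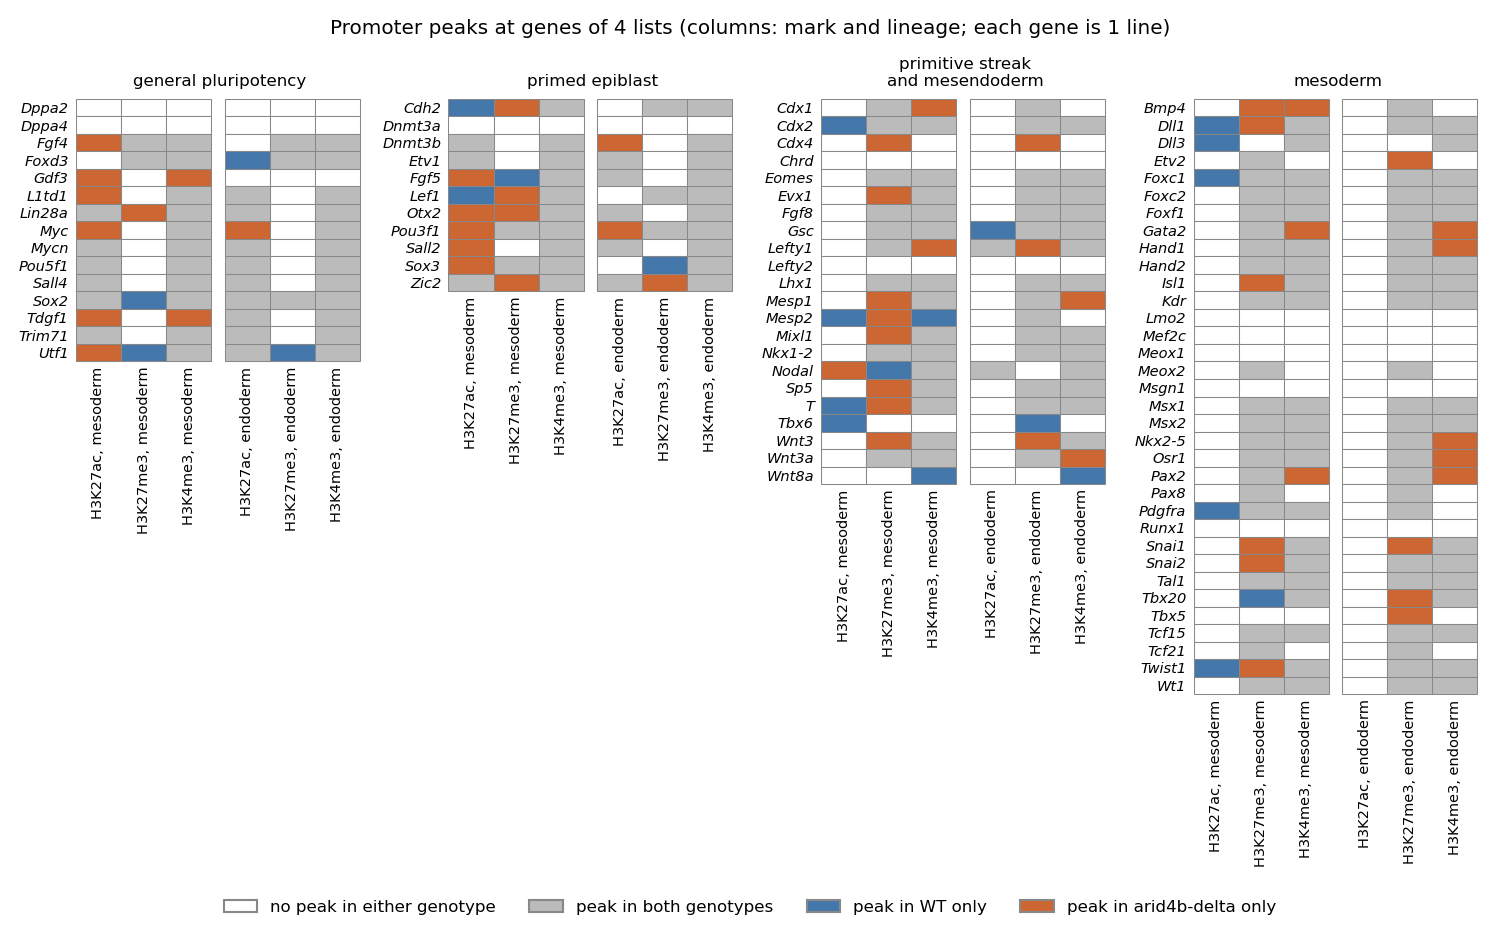
Promoter peaks of the 3 marks (columns, mesoderm then endoderm) at genes (lines) of the general pluripotency, primed epiblast, primitive streak and mesoderm lists, coloured by whether a peak was in neither genotype (white), both (grey), WT only (blue) or arid4b-delta only (orange). In mesoderm H3K27ac, 6 general pluripotency genes were in arid4b-delta only and 5 mesoderm genes in WT only.

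Promoters with peaks of both H3K4me3 and H3K27me3 were more numerous in arid4b-delta. They are called bivalent here, though a peak list does not show whether both marks lie in the same cells. In mesoderm 1585 promoters carried both marks in WT and 2983 in arid4b-delta. Of the 10643 promoters with H3K4me3 alone in WT mesoderm, 1125 (10.6%, 9.99 to 11.2) carried both in arid4b-delta, as did 195 of the 367 with H3K27me3 alone (53.1%, 47.9 to 58.3), and 103 of the 1585 bivalent ones (6.50%, 5.33 to 7.83) had H3K4me3 alone. In endoderm 2100 promoters carried both marks in WT and 2974 in arid4b-delta, with 557 of 9560 H3K4me3-only promoters (5.83%, 5.37 to 6.31) and 519 of 926 H3K27me3-only promoters (56.0%, 52.8 to 59.3) carrying both marks in arid4b-delta. Of the 2100 bivalent ones, 320 (15.2%, 13.7 to 16.8) carried H3K4me3 alone in arid4b-delta. In lists matched in length the moves from H3K4me3 alone to both marks and back were 729 and 527 in mesoderm and 353 and 864 in endoderm, which turned the endoderm direction.

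T, Mesp2, Twist1, Dll1, Bmp7, Fzd10, Smad6, Fgf10 and Wnt5a had mesoderm H3K27ac in WT only and H3K27me3 in arid4b-delta only. They are all 9 genes of the streak, mesoderm and signalling lists with WT H3K27ac and arid4b-delta-only H3K27me3, chosen after their values were seen. Lef1, Cdh2 and Foxa3 showed the same pair of calls, and 90 promoters did so across the genome in mesoderm against 26 with the reverse pair. The 90 are 5.49% of the 1640 promoters with H3K27me3 in arid4b-delta only. The 26 are 17.4% of the 149 with H3K27me3 in WT only. Both pools include promoters that could not show the pair. Only 254 of the 1640 had WT H3K27ac to lose, and the 90 are 35.4% of those. The matching share among the 149 was not computed, so neither pair can be called the more frequent relative to its pool. Utf1, Fgf5, Nodal and Cldn6 had the reverse pair, with H3K27me3 in WT only and H3K27ac in arid4b-delta only. Of these H3K27me3 peaks, those at Fgf5 and Nodal were short and that at Cldn6 had a low -log10 q, as given above. The endoderm counts were 32 and 28. All these pairs come from the full lists and were not recounted in lists matched in length. In matched lists T lost its H3K27me3 call, since the streak genes that kept it were Sp5, Evx1, Mixl1, Mesp2 and Wnt3. Nodal lost its H3K27ac call there.

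H3K27ac away from promoters was also compared, since enhancers set lineage expression. More than 2500 bp from any gene end, endoderm had 5917 peaks in WT and 27375 in arid4b-delta, of which 13.4% (13.02 to 13.8) overlapped a WT peak. Mesoderm had 3926 and 12582 such peaks, with 17.8% (17.1 to 18.5) of the arid4b-delta peaks in the WT list. Conversely 67.8% (66.6 to 69.0) of the WT distal peaks in endoderm and 61.0% (59.5 to 62.6) in mesoderm were in the arid4b-delta list. The distal peaks in arid4b-delta only were weaker and narrower than the shared ones in the same lists, with a median fold enrichment of 5.67 against 8.47 in endoderm and 6.35 against 9.71 in mesoderm, and they numbered 23701 and 10341 in the full lists but 6050 and 4078 in lists matched in length. Within 20000 bp of its promoter, Pou3f1 had 4 distal peaks in arid4b-delta mesoderm and 0 in WT, Fgf4 had 2 and 0, and Tbx6, Twist1 and Pdgfra had 0 and 1, genes chosen after their values were seen.

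The comparison of endoderm with mesoderm within a genotype asks how far the 2 lineages differ in their marks. In WT, H3K27ac was at 728 promoters in endoderm only and at 1383 in mesoderm only. Of the 1383, 824 carried H3K27ac in arid4b-delta mesoderm and 501 in arid4b-delta endoderm. Tbx6, T, Cdx2, Foxc1, Lef1 and Cdh2 were among the WT mesoderm-only promoters without H3K27ac in arid4b-delta mesoderm. Utf1, L1td1, Tdgf1, Fgf5, Otx2, Nodal and Cldn6 had H3K27ac in WT endoderm, arid4b-delta endoderm and arid4b-delta mesoderm, and not in WT mesoderm. Over all promoters, 466 of the 1210 with mesoderm H3K27ac in arid4b-delta only (38.5%, 35.8 to 41.3) were in the WT endoderm list, as were 842 of the 1640 with mesoderm H3K27me3 in arid4b-delta only (51.3%, 48.9 to 53.8). Of the 1178 promoters with endoderm H3K4me3 in arid4b-delta only, 642 (54.5%, 51.6 to 57.4) were in the WT mesoderm list. Of the 864 mesoderm ones, 122 (14.1%, 11.9 to 16.6) were in the WT endoderm list.

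In arid4b-delta, H3K27ac was at 506 promoters in endoderm only and 1619 in mesoderm only. For H3K27me3, 1290 promoters were marked in endoderm only and 216 in mesoderm only in WT, against 685 and 496 in arid4b-delta. With the 2 lists of each genotype matched in length these were 803 and 716 in WT and 427 and 1459 in arid4b-delta, which turned the arid4b-delta direction. For H3K4me3 the counts were 124 and 692 in WT and 74 and 324 in arid4b-delta. Some calls in one genotype only were shared by the 2 lineages. Among promoters unmarked in WT of both lineages, H3K4me3 was in arid4b-delta only in both at 470 promoters, H3K27me3 at 432 and H3K27ac at 203. Among promoters marked in WT of both lineages, 4 were without H3K4me3 in arid4b-delta of both (the Y-linked Uty, Eif2s3y and Ddx3y, and Wnt8a), 17 without H3K27me3 and 145 without H3K27ac. Lists of one genotype overlap between lineages in any case, so these counts show no recurring effect of genotype by themselves. Aebp2, Cbx7, Sox17, Krt19, Zfp42, Gata2 and Pax2 had H3K4me3 in arid4b-delta only in both lineages, Wnt3 and Snai1 H3K27me3 in arid4b-delta only in both, and Utf1 H3K27me3 in WT only in both.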

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

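The tests of a more sensitive H3K27ac list, of exchanged libraries and of the Y-linked promoters below were chosen after the result was seen, and the tests of missed H3K27me3 peaks before it.

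Nanog, a naive pluripotency factor, had an H3K27ac promoter peak in WT only in endoderm (5.95) and in arid4b-delta only in mesoderm (8.65). The nearest peaks of the other genotype lay 4518 and 4266 bp away, and the difference between lineages was not tested. The gene stands out because its genotype difference had opposite directions in the 2 lineages.

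In mesoderm H3K27ac, general pluripotency and primed epiblast promoters that differed were mostly in arid4b-delta only, and streak and mesoderm promoters that differed mostly in WT only. Over all 16 gene lists 17 differing genes were in arid4b-delta only and 28 in WT only, and with each gene's direction drawn at even odds 0.74% of 10000 draws had as large a summed excess of lists towards WT and 32.9% as large a one towards arid4b-delta. An exchange of the arid4b-delta H3K27ac libraries of endoderm and mesoderm is argued against. Among promoters acetylated in 1 lineage only in each genotype, those of WT endoderm were in arid4b-delta endoderm 67 times and mesoderm 198 times. Those of WT mesoderm were so 77 and 400 times (odds ratio 1.76, 1.22 to 2.54). The libraries of the other marks were not tested for an exchange. Both arid4b-delta H3K27me3 lists were closer to WT endoderm than to WT mesoderm. Promoters marked in both lists over those marked in either were 0.644 against 0.474 for endoderm and 0.648 against 0.502 for mesoderm. Both arid4b-delta H3K4me3 lists were closer to WT mesoderm (0.945 against 0.907 and 0.932 against 0.892). For each mark this was the WT list with more marked promoters, so these values do not decide on an exchange. A more sensitive arid4b-delta list does not give the first excess, but the test as a whole leaves a more sensitive list in one genotype open as a candidate explanation. A larger share of less differentiated cells in the arid4b-delta culture and a difference between the genotypes within each cell also stay open and were not tested.

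In mesoderm H3K27me3, streak, mesoderm and signalling promoters that differed were mostly in arid4b-delta only, and the WT list was shorter. For a mark present but missed in WT, a prediction was set. It was that these promoters lack H3K27ac in arid4b-delta no more often than promoters with H3K27me3 in both lists. Of 254 promoters with WT H3K27ac and arid4b-delta-only H3K27me3, 90 had no H3K27ac in arid4b-delta (35.4%, 29.6 to 41.7), against 24.7% at matched H3K27ac fold where both lists had H3K27me3, a difference of 10.7 points (2.40 to 19.4 over 2000 bootstrap draws). At matched fold, 14.4% of promoters with H3K27me3 in neither list had no H3K27ac in arid4b-delta. The 35.4% was above both classes, which argues against missed peaks as the whole account for those promoters. The match was on WT H3K27ac fold only, so weaker H3K27me3 that goes with more H3K27ac loss is not excluded. The bootstrap interval covers promoters and not differences between libraries. For the 1386 without WT H3K27ac, 52.2% (49.6 to 54.9) were in the WT endoderm H3K27me3 list, a value between the bounds set for either outcome, so both missed peaks and a genotype difference stay open there as candidate explanations.

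H3K4me3 at Uty, Eif2s3y and Ddx3y, Y-linked genes, was in WT only in both lineages. Weak peaks missed in arid4b-delta are argued against, since of WT promoters elsewhere with no higher fold 0.784% (0.473 to 1.22) in endoderm and 0.477% in mesoderm had no arid4b-delta peak. Loss of the Y chromosome from the arid4b-delta cells stays open. The arid4b-delta lists held 85 peaks in the first 3 Mb of chromosome Y, 56 of them H3K27ac in endoderm, against 24 in the WT lists. H3K4me3 peaks there numbered 0 in arid4b-delta endoderm against 3 in WT, and 5 in mesoderm of each genotype. With no genome sequence at hand it was not checked whether these positions have near-copies elsewhere.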

How the results depend on the processing

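Of the recomputed main counts and shares, 137 stayed within their limits, 130 moved beyond them and 7 changed direction. A count stayed when it was within 1.5 times the reported one, and a share when it was inside its 95% counting interval. The alternatives added after the data were seen are either gene end as promoter, ends assigned from WT alone, a peak anywhere in the gene or within 1000 bp of it, and absence from both lists of the other genotype, together with the 2500 bp window for gene lists. Every count and share of promoters kept its limits under either gene end, ends from WT alone and chromosomes 1 to 19, and distal peaks did so beyond 5000 bp. Both H3K4me3 shares and the mesoderm H3K27me3 share stayed above 50% under every alternative run. The 7 that changed direction were shares of promoters in arid4b-delta only: endoderm H3K27me3 in matched lists (36.2%), mesoderm H3K27ac in matched lists (26.2%) and with peaks of at least 500 bp (47.4%), and endoderm H3K27ac in the upper 50% of each list (68.4%), against both lists (58.0%), over whole genes (67.4%) and at 2500 bp windows (52.9%). The reported endoderm H3K27ac share has an interval that includes 50%. No depth is given, so none of these alternatives corrects for it. No test paired by lineage was run, and leaving out replicates was not run because each group has 1 library. The alternative with the 5-prime-most TSS of each gene was not run, since the gene table holds no transcripts. The cause of each move was not tested, apart from the construction of the setting itself: matched lists are shorter in arid4b-delta, and longer minimum overlaps or widths remove peaks.

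Values beyond their limits follow, with pairs given as endoderm then mesoderm. Matched lists keep the highest peaks of each list up to the length of the shorter one, and the upper 50% keeps that part of each list by fold enrichment. In matched lists, promoters in arid4b-delta only numbered 663 and 1053 for H3K27me3 and 442 and 571 for H3K27ac. In matched lists, promoters in WT only numbered 45 and 91 for H3K4me3, 1169 and 671 for H3K27me3 and 1806 and 1605 for H3K27ac. In matched lists, the share in arid4b-delta only was 95.8% and 87.5% for H3K4me3, 36.2% and 61.1% for H3K27me3 and 19.7% and 26.2% for H3K27ac. In matched lists, WT peaks that overlapped an arid4b-delta peak were 97.0% and 95.6% for H3K4me3, 36.3% and 49.5% for H3K27me3 and 55.9% and 59.3% for H3K27ac. In matched lists, arid4b-delta peaks that overlapped a WT peak were 72.9% and 78.6% for H3K4me3, 31.7% and 33.5% for H3K27me3 and 51.0% and 57.6% for H3K27ac. In matched lists, H3K4me3-only promoters that carried both marks in arid4b-delta numbered 353 and 729, and the reverse move 864 and 527, which turned the direction in endoderm. Distal H3K27ac peaks in arid4b-delta only numbered 6050 and 4078 there. H3K27me3 promoters in endoderm only and mesoderm only numbered 803 and 716 in WT and 427 and 1459 in arid4b-delta, which turned the arid4b-delta direction, and H3K27ac promoters in endoderm only in arid4b-delta 292. In the upper 50%, promoters in arid4b-delta only numbered 1928 and 1890 for H3K4me3. In the upper 50%, promoters in WT only numbered 303 and 230 for H3K4me3, 656 and 456 for H3K27me3 and 606 for H3K27ac in endoderm. In the upper 50%, the share in arid4b-delta only was 86.4% and 89.2% for H3K4me3, 60.4% and 73.1% for H3K27me3 and 68.4% and 66.2% for H3K27ac. In the upper 50%, WT peaks that overlapped an arid4b-delta peak were 94.8% and 96.7% for H3K4me3, 37.6% and 45.0% for H3K27me3 and 78.1% and 79.1% for H3K27ac. In the upper 50%, arid4b-delta peaks that overlapped a WT peak were 74.3% and 74.5% for H3K4me3, 21.2% and 20.6% for H3K27me3 and 31.4% and 45.5% for H3K27ac.

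At 500 bp covered, promoters in arid4b-delta only numbered 2065 for H3K4me3 in endoderm and 425 and 736 for H3K27ac. At 500 bp covered, promoters in WT only numbered 11 for H3K4me3 in endoderm, 255 and 71 for H3K27me3 and 614 for H3K27ac in endoderm. At 500 bp covered, the share in arid4b-delta only was 99.5% and 98.2% for H3K4me3, 74.9% and 95.2% for H3K27me3 and 40.9% and 54.6% for H3K27ac. With 500 bp peaks, promoters in arid4b-delta only numbered 2744 and 1455 for H3K4me3 and 446 and 606 for H3K27ac. With 500 bp peaks, promoters in WT only numbered 12 and 50 for H3K4me3, 237 and 84 for H3K27me3 and 558 for H3K27ac in endoderm. With 500 bp peaks, the share in arid4b-delta only was 99.6% for H3K4me3 in endoderm, 78.3% and 94.6% for H3K27me3 and 44.4% and 47.4% for H3K27ac. Against both lists, promoters in arid4b-delta only numbered 536 for H3K4me3 in endoderm, 798 for H3K27me3 in mesoderm and 469 and 744 for H3K27ac. Against both lists, promoters in WT only numbered 4 for H3K4me3 in endoderm, 98 for H3K27me3 in mesoderm and 340 for H3K27ac in endoderm. Against both lists, the share in arid4b-delta only was 99.3% for H3K4me3 in endoderm, 74.3% and 89.1% for H3K27me3 and 58.0% and 54.3% for H3K27ac. At 50% peak coverage, WT peaks that overlapped an arid4b-delta peak were 97.3% and 96.5% for H3K4me3, 46.7% and 64.5% for H3K27me3 and 62.0% and 66.8% for H3K27ac. At 50% peak coverage, arid4b-delta peaks that overlapped a WT peak were 52.6% and 57.4% for H3K4me3, 20.5% and 13.6% for H3K27me3 and 22.8% and 34.7% for H3K27ac. Within 1000 bp, WT peaks that overlapped an arid4b-delta peak were 98.9% and 99.1% for H3K4me3, 62.4% and 73.1% for H3K27me3 and 84.0% and 82.8% for H3K27ac. Within 1000 bp, arid4b-delta peaks that overlapped a WT peak were 79.7% and 77.8% for H3K4me3, 37.1% and 35.0% for H3K27me3 and 32.8% and 50.2% for H3K27ac. At 500 bp windows, the share in arid4b-delta only was 66.9% for H3K27me3 in endoderm. Over whole genes, promoters in arid4b-delta only numbered 1733 for H3K27me3 in endoderm and 2245 and 2031 for H3K27ac. Over whole genes, promoters in WT only numbered 701 and 326 for H3K27me3. Over whole genes, the share in arid4b-delta only was 86.3% for H3K27me3 in mesoderm and 67.4% and 69.2% for H3K27ac. At 2500 bp windows, the share in arid4b-delta only was 52.9% for H3K27ac in endoderm.

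Of the recomputed counts of gene lists, 63 stayed within 1.5 times the reported one. The 24 that did not all belong to 1 of 3 settings. Absence from both lists gave, in genes, 2 mesoderm, 1 neuroectoderm, 1 fibroblast, 4 Hox and 0 signalling in endoderm H3K4me3 (arid4b-delta only), and 2 mesoderm in endoderm H3K27me3 (arid4b-delta only). It also gave 0 naive pluripotency, 2 primed epiblast, 2 streak, 1 mesoderm, 0 neuroectoderm, 1 extraembryonic endoderm and 2 signalling in mesoderm H3K27me3 (arid4b-delta only), and 3 general pluripotency and 2 primed epiblast in mesoderm H3K27ac (arid4b-delta only). It also gave 3 signalling in mesoderm H3K27ac (WT only). The 2500 bp window gave 2 endoderm in mesoderm H3K4me3 (arid4b-delta only), and 8 Hox in mesoderm H3K27ac (WT only). Matched lists gave 4 Hox in mesoderm H3K4me3 (arid4b-delta only), and 5 Hox in mesoderm H3K4me3 (WT only). They also gave 1 streak and 1 germline in endoderm H3K27me3 (arid4b-delta only), and 5 streak and 1 extraembryonic endoderm in mesoderm H3K27me3 (arid4b-delta only).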

Other observations

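The protocadherin and histone gene groups below were chosen after their values were seen. Clustered protocadherin genes, which encode cell-surface adhesion proteins of neurons, carried H3K27me3 at more gene ends in arid4b-delta in both lineages. Of the 22 Pcdhb genes on chromosome 18 (37264998 to 37521419, mm10), 3 were marked in WT and 15 in arid4b-delta endoderm, and 1 and 13 in mesoderm, with 12 in arid4b-delta only in each. Among the 14 Pcdha genes (36930285 to 37188897) 6 and 13 were marked in endoderm and 3 and 11 in mesoderm, and among the 21 Pcdhg genes (37661775 to 37841873) 14 and 18, and 9 and 18. H3K4me3 at Pcdha was at 2 gene ends in WT and 8 in arid4b-delta endoderm and at 5 and 12 in mesoderm, and at Pcdhg at 9 and 18 and at 12 and 20, while Pcdhb had at most 1. No gene of the 3 groups had H3K27ac. These counts are from the full lists and were not repeated in lists matched in length. The genes of each group lie side by side, and the spans of the Pcdha genes share an end, as do those of the Pcdhg genes, so the counts of all 3 groups are not of independent promoters.

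The replication-dependent histone gene cluster of chromosome 13 (53 genes, 21715711 to 23934913) held 41 of the 100 H3K27ac peaks with the highest fold enrichment in arid4b-delta endoderm and 15 of those in WT. In mesoderm it held 39 and 20. The longest H3K27ac peaks were 14.7 kb in both arid4b-delta lists, and 4.01 kb in endoderm and 4.21 kb in mesoderm in WT. Of the 10341 distal H3K27ac peaks in arid4b-delta mesoderm only, 62.5% (95% interval 61.5 to 63.4) were in the arid4b-delta endoderm list and 21.9% (21.1 to 22.7) in the WT endoderm list. For the 1530 in WT mesoderm only these shares were 9.41% and 14.6%. Chromosome Y as a whole had 550 H3K27ac peaks in arid4b-delta endoderm and 181 in mesoderm, against 42 in each WT list.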
